A study of Arabidopsis thaliana with 15 samples.

How the data were processed

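Gene expression was measured in whole Arabidopsis seedlings on 15 one-colour Affymetrix ATH1 arrays, each hybridised with biotin-labelled target made from total RNA. The wild type was Landsberg erecta (WT). The phyAphyB double mutant carries the alleles phyA-201 and phyB-5, and YHB stands for transgenic lines of that mutant expressing a phytochrome B allele with a tyrosine-to-histidine change. Seedlings grew for 4 days in darkness or in continuous red light (Rc) at 15 or 50 µmol per square metre per second, after 4 days of stratification at 4 °C and 3 h of white light at 80 µmol per square metre per second. The arrays formed 6 groups: WT dark, phyAphyB dark and YHB dark with 3 arrays each, and WT Rc15, WT Rc50 and YHB Rc50 with 2 each. Replicates were independent biological samples, per the series text.

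The deposited values were linear signal intensities made with GCOS, per the labels' protocols; the GCOS version and its settings are not given in the sources used here. The table held 22810 probe sets, of which 64 control probe sets were left out and 22746 were tested. Array medians ran from 18.33 to 48.253, a ratio of 2.6325, so the arrays were scaled. Each array was multiplied so that its median equalled the common median of 29.494, and log2(value + 16) was taken. Fold changes are on that scale, which understates the change of dim probe sets, so the order of genes that are near background in a group depends on the added value. The number of arrays limits the precision.

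Comparisons, tests, lists of genes, the rule for naming genes and most other settings to be tried were fixed before the data were examined. The planned wording for arrays of unequal level was to set each array's log2 median to a common median, which read literally centres the values after the log. Scaling ahead of the log was chosen once the array medians had been seen and before any fold change was computed. The literal order was run as the alternative in which each array is centred on its own median of log2 values, and its results are in the closing section. Further lists, a trimmed-mean scaling, a fit without scaling and several single genes were added later and are named as such where they are used.

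A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend). It had 9 residual degrees of freedom and a prior of 6.54. P-values are limma's, adjusted by Benjamini-Hochberg over the 22746 probe sets of a comparison. A probe set passed at an adjusted p under 0.05 and a change of at least 2-fold, and "rose" and "fell" are used only for what passed. Errors of changes are standard errors from the fit. On simulated data for YHB dark minus phyAphyB dark, with 22746 genes and 50 changed at each size, 52% of 2-fold changes and 100% of 3-fold, 4-fold and 8-fold changes were recovered, with 3 false calls. On simulated data for WT Rc50 minus WT dark, 56% of 2-fold changes and 100% of the larger ones were recovered, with 1 false call. Of simulated lists of 9 genes in YHB dark minus phyAphyB dark, 8 of 8 shifted lists and 1 of 200 unshifted lists passed. The changed genes and the lists were drawn from probe sets brighter than the median, with noise independent between genes. These simulations therefore cover neither dim probe sets nor correlated genes in a list. The low recovery at 2-fold follows from the threshold for passing, which lies at that size.

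Genes were named from the platform's probe table, in which 13513 of the tested probe sets had 1 gene, 503 had several and 8730 had none. Of those with 1 gene, 13436 matched a locus of the TAIR10.1 annotation. The 13513 probe sets with 1 gene covered 13350 distinct genes, and 1580 of these probe sets had a symbol other than a locus number. The annotation was used for names only. Of 23 lists with 352 entries, 50 entries had a named probe set, and the 9 lists with at least 3 of them were tested. With named members out of all entries, these cover the light-harvesting antenna (3 of 20), photosystems and electron transport (5 of 30), the Calvin cycle (3 of 17) and photorespiration (3 of 11). The others are tetrapyrrole and chlorophyll synthesis (9 of 30), shade and elongation markers (4 of 17), auxin response (3 of 18), gibberellin genes (3 of 19) and flavonoid synthesis (3 of 20). A list result holds for its named members only. A list was tested with limma's camera at a preset correlation of 0.01, using 1 probe set per gene (the one with the highest mean), and adjusted over the lists of a comparison; camera with an estimated correlation was run beside it. Counts adjusted over the list alone equalled those over all probe sets for each of the 9 lists. Another 33 lists were written after the gene names had been seen and before fold changes were computed.

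Genes named in the report are the largest changes in each direction (up to 5) among probe sets that passed, match 1 gene, have a mean above the median of all probe sets in the higher group, and show no overlap between arrays. For the difference between the responses overlap was not checked, and the mean was that of the highest of its groups. In the main comparisons they also include the largest members of the lists with the smallest p. The rule also named PHYA and PHYB, but the probe table names neither, so their levels were not analysed here. A shared response was measured by the overlap of passing probe sets and by the correlation and covariance of log2 changes across probe sets, which are not independent replicates. Alternatives covered the value added before the log (1 or 64), quantile normalization, centred log2 values, trimmed-mean scaling, no scaling, omission of the dimmest 40% of probe sets, fits on only the groups compared, eBayes without trend, array weights, the replicate number as a block, a term for the wording of the labelling protocol, other fold thresholds, and the omission of each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

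Some features of the design limit what the comparisons can show. Dark-grown seedlings had a temperature cycle of 12 h at 22 °C and 12 h at 18 °C for the opening 2 days and 20 °C afterwards, whereas seedlings in red light were kept at 20 °C, so light cannot be told apart from temperature regime. Dark YHB samples came from 2 transgenic lines, and the labels do not tie arrays to lines, so the line was not modelled. The series text counts 16 samples and itemises 15, and 15 were analysed.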

Results

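Transcript levels were measured as array signal in dark-grown and red-light-grown seedlings of the wild type, the phyAphyB mutant and YHB, with 15 arrays in 6 groups. The median signal per array ran from 18.33 to 48.253 before scaling. After scaling, log2 values of arrays of the same group correlated at 0.98 to 0.99 across probe sets. Arrays of WT dark and phyAphyB dark correlated at 0.979 to 0.988, arrays of YHB dark and WT dark at 0.896 to 0.918, and arrays of YHB dark and WT Rc50 at 0.956 to 0.97. Across the 15 arrays the leading principal component held 59.2% of the variance and the next 12.8%.

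WT Rc50 minus WT dark (2 against 3 arrays) measured the response of the wild type to red light. The photosynthesis lists moved up together, and counts of list members here and below are of those named on the array. All 5 photosystem and electron transport genes rose, with a median log2 change of 1.7 (camera, adjusted p = 7.63e-08), led by the photosystem I subunit PSAN at 2.16 ± 0.23 (SE). In the light-harvesting antenna, 2 of 3 genes rose (median 1.59, adjusted p = 0.000145), with LHCB4.2 at 2.4 ± 0.19. All 3 Calvin cycle genes rose (median 1.5, adjusted p = 0.000145), among them SBPASE at 1.58 and RCA, which encodes Rubisco activase, at 1.5. Of the photorespiration genes, 2 of 3 rose (median 1.24, adjusted p = 0.000468). Of 9 tetrapyrrole genes, 3 rose (median 0.78, adjusted p = 0.000468), with HEME1 at 1.41 ± 0.15. Elongation genes went the other way: all 4 shade markers fell (median -1.85, adjusted p = 4.74e-06), including IAA29 at -2.07, XTH33, a cell wall xyloglucan enzyme, at -1.97, and HAT2 at -1.74. Of 3 auxin genes 2 fell (median -1.25, adjusted p = 0.000145), IAA29 and WES1 at -1.25. Flavonoid genes shifted up as a list (median 0.55, adjusted p = 0.00406) with no member passing, and gibberellin genes did not shift (median -0.36, adjusted p = 0.245). Each of these list shifts also held with an estimated correlation.

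Among the largest rises in that comparison was that of AT5G48490, a lipid-transfer family gene, at 5.02 ± 0.35 (32.4-fold, adjusted p = 1.08e-07). AT5G38980 rose by 4.56 and AT3G57020, of the strictosidine synthase family, by 4.19. The seed oil-body gene OLEO3 fell, at -4.16 ± 0.16 (17.9-fold lower, adjusted p = 2.83e-10), as did AT4G35720 at -3.55 and the lipid-transfer family gene AT4G22490 at -3.53. In all, 891 probe sets were higher and 660 lower, and 735 of the 1551 were named to 1 gene; without scaling 1150 were higher and 426 lower. The scaled signal of AT5G48490 in WT dark was close to the added value of 16, so its change was 5.99 with pseudocount 1 and 3.76 with pseudocount 64, and AT1G22690 (3.83) reached 6.95 with pseudocount 1. PRK (1.08) stayed under 2-fold with quantile normalization (0.85), CHLM (1.2) without WT dark replicate 1 (0.94) or WT Rc50 replicate 2 (0.93), and HEME2 (1.02) without WT dark replicate 1 (0.99) or WT Rc50 replicate 1 (0.85), with pseudocount 64 (0.9) and with a term for the labelling protocol wording (0.95).

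**Figure D1:**
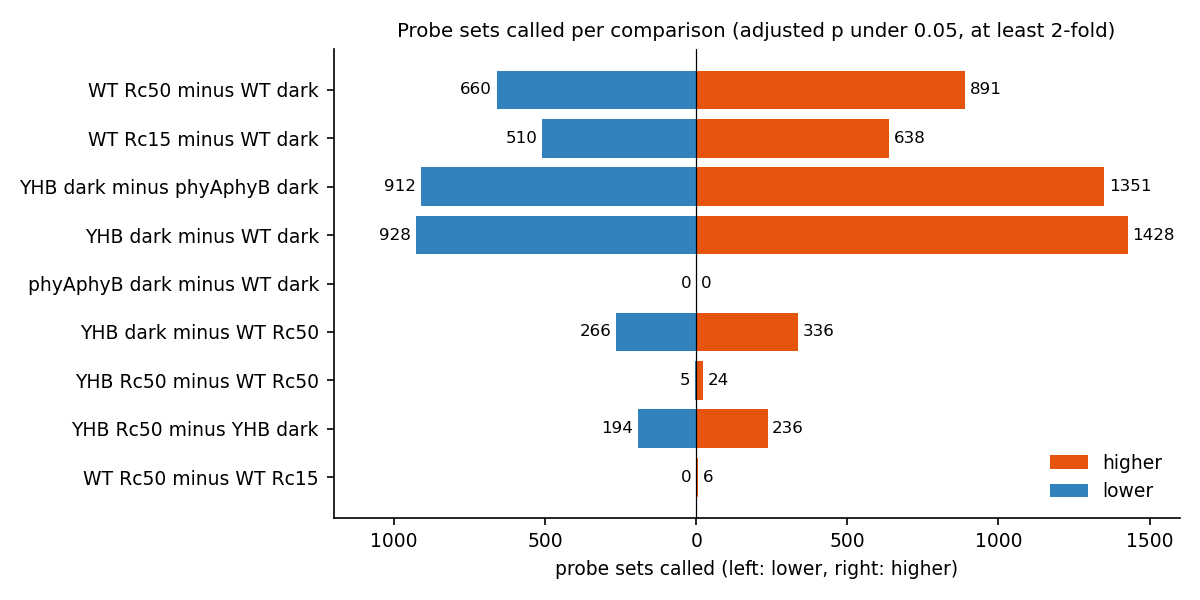
Number of probe sets that were higher or lower in each comparison, at an adjusted p under 0.05 and at least 2-fold. YHB dark minus phyAphyB dark gave 1351 higher and 912 lower, phyAphyB dark minus WT dark gave 0, and YHB Rc50 minus WT Rc50 gave 29 in all.

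The weaker light at 15 µmol per square metre per second, compared with darkness in the wild type (2 against 3 arrays), moved the same groups. All 5 photosystem genes rose (adjusted p = 4.8e-09), as did 2 of 3 antenna genes (adjusted p = 0.000695), 1 of 3 Calvin cycle genes (adjusted p = 0.000493) and 2 of 9 tetrapyrrole genes (adjusted p = 0.000595), while 3 of 4 shade markers (adjusted p = 8.74e-06) and 2 of 3 auxin genes (adjusted p = 0.000333) fell. AT5G48490 rose by 5.79 (55.5-fold), which ran from 4.51 to 6.78 over the alternative settings, AT3G57020 by 3.48 and AT5G38980 by 3.28. OLEO3 fell, at -4.1, as did AT4G22490 at -3.63 and AT4G22460 at -3.32. In this comparison 638 probe sets were higher and 510 lower, or 785 and 292 without scaling. Photorespiration genes, with 1 of 3 rising, shifted at an adjusted p of 0.0415, and adjusted p = 0.166 with an estimated correlation.

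Between the fluence rates, in WT Rc50 minus WT Rc15 (2 against 2 arrays), limma counted 1301 of 22746 probe sets at an unadjusted p under 0.05. A share of 0.05 is reached without any difference. Of the probe sets that passed, 6 were higher and 0 lower. The named one was AT1G65490, at 1.15 (adjusted p = 0.0441). Photorespiration genes shifted up as a list (median 0.61, adjusted p = 0.0032), with adjusted p = 0.215 with an estimated correlation and no member passing. The count of 6 became 0 without WT dark replicate 2, phyAphyB dark replicate 1 or 2, YHB dark replicate 1, 2 or 3, WT Rc15 replicate 1 or 2, or WT Rc50 replicate 1, and 1 without WT dark replicate 3 or YHB Rc50 replicate 1 or 2. AT1G65490 also ceased to pass in each of those omissions, at 1.03 without WT Rc15 replicate 1, 1.27 without WT Rc15 replicate 2, 0.98 without WT Rc50 replicate 1 and 1.15 in the others, and it failed in 19 of the 27 settings in all.

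phyAphyB dark minus WT dark (3 against 3 arrays) addressed whether loss of both phytochromes changes dark-grown seedlings. No named gene or list passed. PSAN had a group mean of 9.54 in phyAphyB dark and 9.37 in WT dark, IAA29 means of 7.54 and 7.31, and OLEO3 means of 9.08 and 9.15. The 9 lists had adjusted p from 0.231 to 0.905. In limma 1125 of the 22746 probe sets had an unadjusted p under 0.05, where a share of 0.05 is reached without any difference. At the threshold for passing 0 probe sets passed, with a smallest adjusted p of 0.056. The count was 1 without phyAphyB dark replicate 3 or either WT Rc50 replicate, 2 without YHB dark replicate 1 or 3, and 8 without either YHB Rc50 replicate.

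YHB dark minus phyAphyB dark (3 against 3 arrays) measured the effect of the transgene in its own background without light. Photosynthesis genes rose in darkness: all 5 photosystem genes (median 1.99, adjusted p = 6.68e-06), 2 of 3 antenna genes (median 1.87, adjusted p = 0.0186), all 3 Calvin cycle genes (median 1.77, adjusted p = 0.000973) and 2 of 3 photorespiration genes (median 1.54, adjusted p = 0.00141). None of these 4 list shifts passed with the other form of the test: the photosystem list had adjusted p = 0.0527 with an estimated correlation, and the others adjusted p = 0.0558 each with an estimated correlation. PSAN rose by 2.32, SBPASE by 1.93 and the photorespiratory hydroxypyruvate reductase gene HPR by 2.52. In the tetrapyrrole list 4 of 9 rose and 1 fell (median 0.98, adjusted p = 0.00247, and adjusted p = 0.0558 with an estimated correlation). CHLM, whose enzyme methylates a chlorophyll precursor, rose by 2.19 and HEME1 by 2.06, whereas PORB, encoding a light-dependent protochlorophyllide oxidoreductase, fell, at -2.16. All 4 shade markers fell (median -1.79, adjusted p = 1.57e-05), including XTH33 at -2.88 and IAA29 at -2.26, as did all 3 auxin genes (median -1.5, adjusted p = 4.63e-05), with WES1 and GH3.3 each at -1.5. Both of these lists held with an estimated correlation. Flavonoid genes (median 0.43, adjusted p = 0.106, 1 of the list rising) and gibberellin genes (median -0.17, adjusted p = 0.132) did not shift.

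AT5G48490 rose by 6.29 ± 0.31 (78.3-fold, adjusted p = 5.57e-10), AT3G57020 by 5.58 (47.8-fold), the thionin gene THI2.2 by 4.69 and the glutaredoxin family gene AT1G64500 by 4.25. The rises of AT5G48490, AT3G57020 and THI2.2 were measured from near background, with log2 means of 5.15, 4.77 and 4.25 in phyAphyB dark. Over the alternative settings they ran from 5.05 to 7.36, 4.16 to 6.72 and 3.01 to 6.98. Among the largest falls were those of AT2G47780 at -4.39, OLEO3 at -4.25, AT4G22490 at -4.17 and the beta-tubulin gene TUB1 at -4.07. In all, 1351 probe sets were higher and 912 lower, and 1118 of the 2263 were named to 1 gene; without scaling 659 were higher and 2597 lower. PRK (1.27) stayed under 2-fold with quantile normalization (0.62), without YHB dark replicate 1 (0.96) and without scaling (0.63), as did the photorespiration gene AT1G11860 (1.54) without scaling (0.9).

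**Figure D2:**
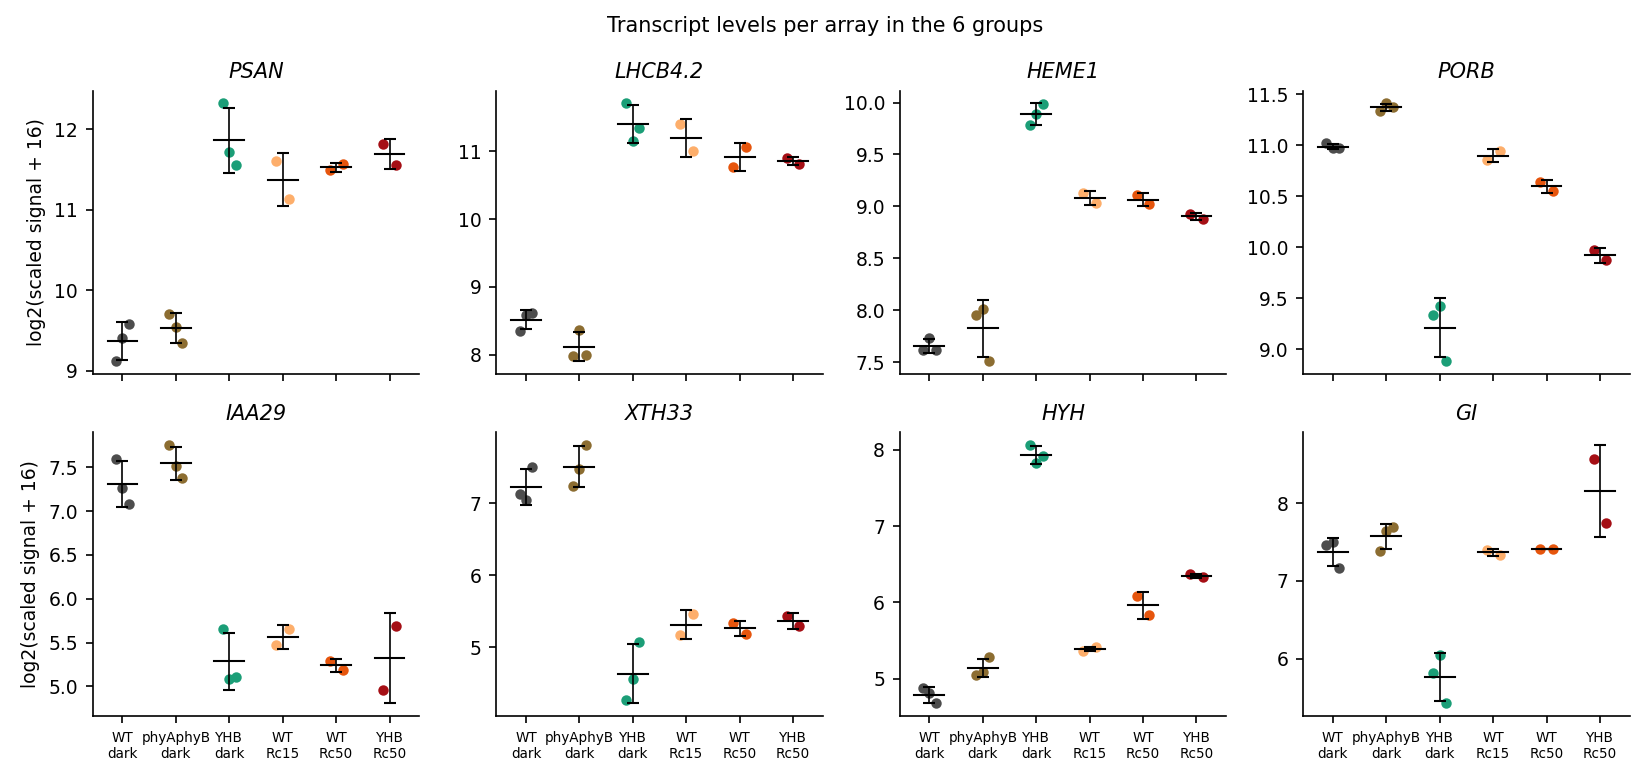
Log2 signal per array (points) with group mean and SD (bars) for 8 genes in the 6 groups. Photosynthesis genes such as PSAN were higher in YHB dark and in red light than in WT dark and phyAphyB dark, IAA29 and XTH33 were lower, and GI was lowest in YHB dark; PORB, HYH and GI were picked after their values were seen.

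YHB dark minus WT dark (3 against 3 arrays) set the transgenic seedlings against the dark wild type. The same lists moved: 5 of 5 photosystem genes (median 2.1, adjusted p = 6.3e-06), 2 of 3 antenna genes (median 1.91, adjusted p = 0.00444), 3 of 3 Calvin cycle genes (median 1.91, adjusted p = 0.000603) and 3 of 3 photorespiration genes (median 1.51, adjusted p = 0.000939) rose. All 4 shade markers (median -1.73, adjusted p = 1.84e-05) and all 3 auxin genes (median -1.29, adjusted p = 0.000156) fell. In the tetrapyrrole list 5 of 9 rose and PORB fell, at -1.77 (median 1.07, adjusted p = 0.00121). Each of these shifts held with an estimated correlation, while flavonoid genes (adjusted p = 0.192) and gibberellin genes (adjusted p = 0.194) did not shift. AT5G48490 rose by 6.42 (85.6-fold), AT3G57020 by 5.72 and THI2.2 by 4.75, and AT2G47780 fell, at -4.54, as did OLEO3 at -4.32, TUB1 at -4.31 and XTH19 at -4.3. The 3 rises, again from near background in the dark control, ran from 5.12 to 7.41, 4.21 to 7.13 and 3.03 to 7.24 over the alternative settings. In this comparison 1428 probe sets were higher and 928 lower, or 837 and 1790 without scaling. AT1G80380, 1 of the 3 photorespiration genes, rose by 1.04 but did not pass with quantile normalization (0.66), centred log2 values (0.88), array weights (1), trimmed-mean scaling (0.89) or no scaling (0.59), or without YHB dark replicate 1 (0.9). PRK, 1 of the 3 Calvin cycle genes, rose by 1.44 and stayed under 2-fold with quantile normalization (0.83) and without scaling (0.99), as did GH3.3, 1 of the 3 auxin genes (-1.29), with pseudocount 64 (-0.96).

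**Figure D3:**
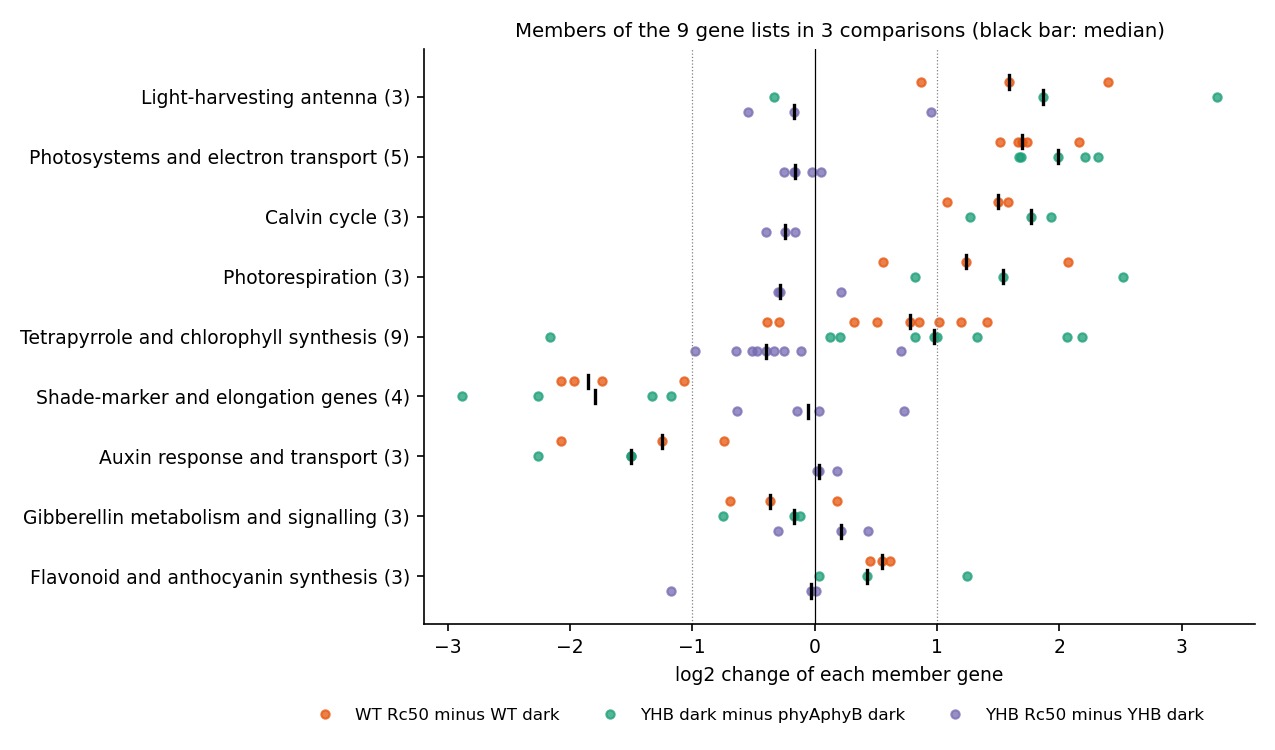
Log2 change of each member of the 9 lists (points) and the list median (black bar) in WT Rc50 minus WT dark, YHB dark minus phyAphyB dark and YHB Rc50 minus YHB dark, with dotted lines at a 2-fold change. Photosystem medians were 1.7 in the wild type under red light and 1.99 in dark YHB, and shade marker medians -1.85 and -1.79.

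The series title asks how far YHB in darkness gives the response to light, and the comparison of both responses uses no array in common. Among the genes that passed in both, AT5G48490, AT3G57020, PSAN and HEME1 rose and OLEO3, IAA29 and XTH33 fell. Of the probe sets that passed in WT Rc50 minus WT dark, 707 were also higher and 470 also lower in YHB dark minus phyAphyB dark, where independent lists would share 52.9 and 26.5. These 1177 made up 75.9% of the wild-type response and 52% of the YHB response, and 5 probe sets passed in opposite directions. Changes correlated at 0.78 across probe sets (covariance 0.284). The 707 had median changes of 1.51 in the wild type and 1.98 in YHB, and the 470 had medians of -1.44 and -1.71. The 641 higher only in YHB had medians of 0.65 in the wild type and 1.25 in YHB, and the 440 lower only in YHB -0.63 and -1.23. Of the 1081 that passed only in YHB, 220 passed the same way in YHB dark minus WT Rc50. Of the 369 that passed only in the wild type, 77 passed the opposite way there. Much of the unshared part thus moved the same way but missed the threshold in 1 of the comparisons. Against WT Rc15, 504 were shared higher and 384 lower, where independent lists would share 37.9 and 20.4, or 77.4% of that response. Against YHB dark minus WT dark, 736 were shared higher and 501 lower, where independent lists would share 55.9 and 26.9, and changes correlated at 0.81 (covariance 0.301). Unchanged groups simulated against the same 3 WT dark arrays gave a correlation of 0.45, a covariance of 0.013 and 0 shared passing probe sets, so the covariance exceeded the simulated one by 0.288. The 3 dark arrays cannot be split into parts of at least 2, so part of the overlap and of the correlation of 0.81 may come from the shared controls.

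YHB dark minus WT Rc50 (3 against 2 arrays) measured how dark YHB differed from the wild type in red light. Higher in dark YHB were rpl16 at 3.45 and rpl14 at 3.09, which encode plastid ribosomal proteins, AT5G22390 at 2.85 and the peroxidase family gene AT5G64110 at 2.68. Both rpl genes belong to 22 plastid-encoded gene expression genes, a list added later, of which 12 were higher and 10 did not pass (adjusted p = 1.7e-11, and adjusted p = 0.268 with an estimated correlation). Lower in dark YHB were the late embryogenesis abundant (LEA) family genes AT3G02480 at -3.72 and AT3G15670 at -3, and the transporter gene OCT1 at -2.69. None of the 9 lists shifted (adjusted p from 0.298 to 0.861), and PORB, at -1.38, was the 1 list member that passed. In all, 336 probe sets were higher and 266 lower, or 264 and 141 without WT Rc50 replicate 1. That balance turned with the scaling, to 233 higher and 326 lower with quantile normalization, 225 and 371 with centred log2 values, 238 and 355 with trimmed-mean scaling, and 47 and 1127 without scaling. Of the 1177 shared probe sets, 159 also passed here, and 154 of them had gone further in YHB.

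YHB Rc50 minus WT Rc50 (2 against 2 arrays) compared the genotypes under the same light. AT2G25450, a dioxygenase family gene, rose by 1.53 (adjusted p = 0.00427), the glucosyltransferase gene UGT84A3 rose by 1.52 (adjusted p = 0.00954), and AT3G22620 fell, at -1.25 (adjusted p = 0.0295). Flavonoid genes were lower as a list (median -0.53, adjusted p = 0.000322), which held with an estimated correlation, with no member passing, and the other lists did not shift (adjusted p from 0.304 to 0.597). In all, 24 probe sets were higher and 5 lower, and 12 of the 29 were named to 1 gene. The count was 5 without WT Rc50 replicate 1, 4 without replicate 2, 11 without YHB Rc50 replicate 1, 154 without replicate 2, 17 without phyAphyB dark replicate 2, 11 without either WT Rc15 replicate, and 0 in a fit on these groups alone. AT2G25450 did not pass with pseudocount 64 (0.66) or without WT Rc50 replicate 1 (1.48) or 2 (1.59), nor UGT84A3 with pseudocount 1 (1.86) or 64 (0.97), without scaling (1.35), or without WT Rc50 replicate 1 (1.6) or 2 (1.43) or YHB Rc50 replicate 1 (1.15), nor AT3G22620 without scaling (-1.48) or without WT Rc50 replicate 1 (-0.92), YHB Rc50 replicate 1 (-1.34) or either WT Rc15 replicate (-1.25).

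YHB Rc50 minus YHB dark (2 against 3 arrays) asked whether red light still changed expression in YHB. The largest falls included those of the plastid-encoded genes rpl16 at -3.69, rpl14 at -3.58, ndhH, for an NAD(P)H dehydrogenase subunit, at -2.98 and atpH, for an ATP synthase subunit, at -2.49. Of 65 plastid-encoded genes 28 fell and the others did not pass, and in the list of 22 gene expression genes 13 fell (adjusted p = 2.72e-15, and adjusted p = 0.203 with an estimated correlation). Of 16 mitochondrion-encoded genes, whose transcripts also lack a stable poly(A) tail, 2 fell (median -0.12), and the 3 brighter than the median probe set had a median of -0.79. AT4G34950 rose by 2.93, AT4G23680 by 2.85 and the alkenal reductase gene AER by 2.46 ± 0.14 (adjusted p = 3.39e-07). None of the 9 lists shifted (adjusted p from 0.122 to 0.875), and the flavonoid glycosyltransferase gene UGT78D1 was the 1 member that passed, at -1.17. In all, 236 probe sets were higher and 194 lower, or 310 and 148 with centred log2 values, 90 and 100 with pseudocount 64, and 316 and 40 without scaling. The LEA family gene AT3G02480 (2.77) did not pass without YHB dark replicate 2 (2.31) or YHB Rc50 replicate 1 (2.83) or 2 (2.71), nor UGT78D1 without YHB Rc50 replicate 1 (-0.98), with pseudocount 64 (-0.66) or without scaling (-0.82).

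**Figure D4:**
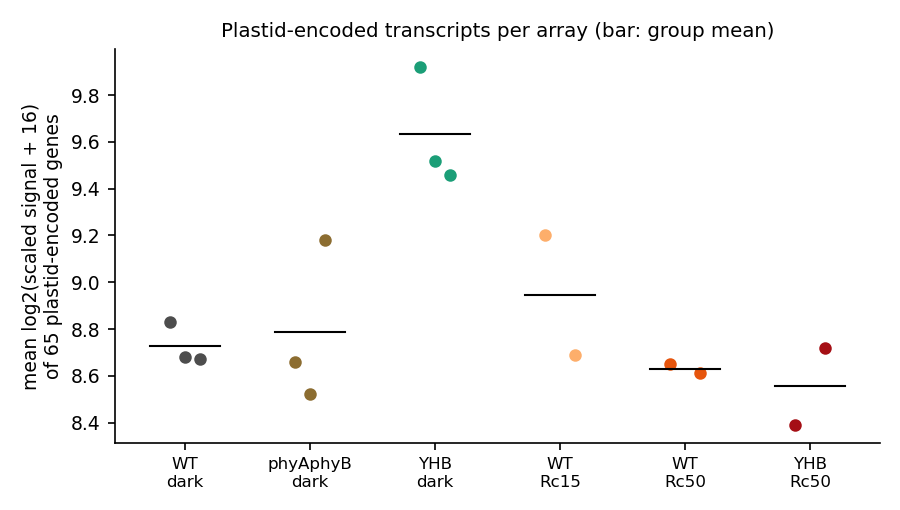
Mean log2 signal of 65 plastid-encoded genes on each of the 15 arrays, by group. The 3 YHB dark arrays had means of 9.92, 9.52 and 9.46 and the 2 YHB Rc50 arrays means of 8.39 and 8.72.

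The difference between the responses, (YHB Rc50 minus YHB dark) minus (WT Rc50 minus WT dark), tested whether the change from darkness to red light differed in YHB. It was negative for genes that light raised in the wild type, such as AT5G48490 at -7.24 and AT3G57020 at -5.28, and positive for genes that light lowered, such as AT4G22490 at 4.52 and OLEO3 at 3.9. Opposite signs arise wherever YHB changed little, so they are no separate evidence of a different action of red light. OLEO3 was near background in YHB, with log2 means of 4.83 in YHB dark and 4.57 in YHB Rc50. With little room to fall there, its difference mainly mirrors its fall of -4.16 in the wild type. Photosystem genes had a median difference of -1.9 (adjusted p = 1.55e-06) and shade markers one of 1.61 (adjusted p = 3.88e-05). In all, 832 probe sets were higher and 1151 lower in this test, or 338 and 374 without scaling and 372 and 698 with pseudocount 64. The wild-type and YHB responses to red light shared 65 probe sets in the same direction and 74 in opposite directions, and their changes correlated at 0.03 across probe sets. The 65 were 48 higher and 17 lower, where independent lists would share 9.2 and 5.6. No such value was computed for the 74 in opposite directions, so the 65 alone do not show a shared response.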

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

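The difference between the responses, its lists and the splits of the dark arrays were planned; the tests that weigh explanations were chosen only after the results had been seen.

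The change from darkness to red light differed between YHB and the wild type for 1983 probe sets in the test of both responses. Without scaling 712 passed, and 1070 with pseudocount 64. This difference equals YHB minus WT in red light less YHB minus WT in darkness. Those comparisons passed for 29 and 2356 probe sets, so the test mainly restates the dark difference between the genotypes. Among named genes the difference was 4.52 for AT4G22490, 3.9 for OLEO3, 3.83 for AT4G35720, 3.58 for AT5G19100 and 3.54 for AT2G34020. It was -7.24 for AT5G48490, -5.28 for AT3G57020, -4.48 for AT2G34620, -4.14 for THI2.2 and -4.02 for AT5G35970. In YHB dark OLEO3, AT4G35720, AT5G19100 and AT2G34020 had log2 means of 4.83, 4.48, 4.57 and 4.43, near background, where the median of all probe sets was 5.54. They had little room to fall further, so their positive differences do not show that red light acted differently. AT4G22490 had a mean of 6.04 there. Such a floor was not tested for the lowered probe sets as a set. Of the lists, the antenna had a median difference of -1.76 (adjusted p = 0.00381), photosystems -1.9 (1.55e-06), the Calvin cycle -1.66 (0.000298), photorespiration -1.54 (0.00321), tetrapyrrole genes -1.02 (0.000185), shade markers 1.61 (3.88e-05), auxin genes 1.27 (0.000185) and flavonoid genes -0.58 (0.00275). With an estimated correlation photorespiration no longer passed (adjusted p = 0.0531 with an estimated correlation), and gibberellin genes did not shift (median 0.26, adjusted p = 0.14).

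The weak response of YHB to red light goes against a temperature regime that moves the genes in every genotype: the 1551 probe sets of the wild-type response, signed by it, had a median change of -0.07 in YHB (quartiles -0.4 and 0.27) against 1.38 in the wild type. Signals at the upper end of the array are argued against too. In dark YHB 415 of the 891 raised probe sets had a mean below a log2 level of 8.19. That level bounds the brightest 10% of probe sets by their mean over all arrays. These 415 still had a median change of 0.05 in YHB, against 1.28 in the wild type. That YHB already gives the response in darkness is a candidate explanation, as 75.9% of the wild-type response passed in the same direction in YHB dark minus phyAphyB dark. A regime effect that acts only without an active phytochrome, or one that light offsets in YHB, stays open, since light and regime are confounded in every genotype.

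The 65 plastid-encoded genes had a median change of 0.78 in YHB dark minus phyAphyB dark (23 passing as higher), 1.02 in YHB dark minus WT Rc50 (29 higher) and -1.01 in YHB Rc50 minus YHB dark (28 lower), but -0.08 in the wild type under red light. The scaling of the arrays is argued against, as the smallest median over 3 other scalings was -0.84; without scaling it was -0.56, where that of all probe sets was 0.15. For the 43 photosystem, ATP synthase, Rubisco and NDH genes the median was 0.15 in the wild type (quartiles -0.24 and 0.45) against -0.83 in YHB. This argues against a regime effect as the only cause of the change in these genes. A shared regime effect that light offsets in the wild type cannot be told apart, since the wild-type change holds both. For all 65 genes the median was 0.86 in YHB dark minus WT dark and -0.01 in YHB Rc50 minus WT Rc50. For the 22 gene expression genes, with medians of -0.52 in the wild type and -1.27 in YHB, a regime effect cannot be told apart from light either. The dark groups had the same regime, so a regime effect common to all genotypes does not account for their difference. Of the 65 genes, which include these 22, 25 were higher and 0 lower in YHB dark minus WT dark, and 1 had a change below 0. Priming or recovery of RNA without a poly(A) tail also cannot be told apart: the 16 mitochondrion-encoded genes had a median of -0.12, but only 3 were brighter than the median probe set, and those had a median of -0.79. A biological effect of YHB on plastid transcripts stays open and may differ between the transgenic lines, which the labels do not assign to arrays.

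More probe sets were higher than lower in dark YHB, 60.6% against WT dark and 59.7% against phyAphyB dark. With trimmed-mean scaling these shares were 50.9% and 51%, and without scaling they were 31.9% and 20.2%, so the excess is consistent with the choice of the level to which arrays were scaled. Median signal before scaling was lowest in YHB dark, at 22.53 (SD 3.871, n = 3) against 31.29 in WT dark and 35.21 in phyAphyB dark. The 100 brightest probe sets held 14.1% of the signal in YHB dark (SD 1.91, n = 3) and 10.73% in WT dark (SD 1.16, n = 3). No biological explanation of the excess was tested.

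For each pair of dark groups the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split of YHB dark and phyAphyB dark gave 2263 passing probe sets and the highest of the other splits 0, and only 1 split reached the real value. The real split of YHB dark and WT dark gave 2356 and the highest other 0, again with 1 split. For phyAphyB dark and WT dark the real split gave 0 and the highest other 2. All 10 splits reach a count of 0 by definition, so that result decides nothing. In the pairs with YHB the other splits mix YHB and control arrays within a group. That adds their difference to the spread, so the counts of 0 there are no reference for the real split.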

How the results depend on the processing

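Trimmed-mean scaling, which leaves out 2% of probe sets at each end, and the fit without scaling were chosen after seeing the data; the other alternatives were planned. None of the 165 results for named genes that were followed through the settings changed sign in any of them. More probe sets were lower than higher, against the reported balance, in YHB dark minus WT Rc50 with quantile normalization, centred log2 values, trimmed-mean scaling and no scaling, in YHB dark minus phyAphyB dark (659 and 2597) and YHB dark minus WT dark (837 and 1790) without scaling, in YHB Rc50 minus YHB dark with pseudocount 64 (90 and 100) and by adjusted p alone (974 and 1003), and in WT Rc15 minus WT dark by adjusted p alone (1557 and 1597). Of 150 list medians 36 changed sign with another scaling or none, 4 of them in lists that passed, 3 with centred log2 values and 1 without scaling. In the order WT Rc50 minus WT dark, WT Rc15 minus WT dark, YHB dark minus phyAphyB dark, YHB dark minus WT dark, YHB dark minus WT Rc50 and YHB Rc50 minus YHB dark, the counts were 2482, 1828, 3758, 3903, 1107 and 856 with pseudocount 1, and 759, 553, 1265, 1335, 251 and 190 with pseudocount 64. They were 4333, 3154, 7060, 7117, 2662 and 1977 by adjusted p alone, and 3485, 2610, 4741, 4870, 2059 and 1577 at 1.5-fold. The difference between the responses gave 1070 with pseudocount 64, 3201 by adjusted p alone and 3143 at 1.5-fold. These changes follow from what each setting counts.

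YHB Rc50 minus WT Rc50 gave 12 with pseudocount 1, 12 with pseudocount 64, 51 with centred log2 values, 5 without scaling and 0 with only the groups compared. phyAphyB dark minus WT dark gave 1 with pseudocount 1, 1 with quantile normalization, 8 with centred log2 values, 1 with the dimmest 40% of probe sets left out and 2 with trimmed-mean scaling. WT Rc50 minus WT Rc15 gave 0 with pseudocount 1, 1 with pseudocount 64, 3 with quantile normalization, 22 with centred log2 values, 1 without trend, 24 with array weights, 1 without scaling, and 0 with the wording term, with trimmed-mean scaling and with only the groups compared. Without scaling YHB dark minus WT Rc50 gave 1174 and the difference between the responses 712. The cause was not tested.

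The replicate numbers gave no clear sign of paired samples: of 33 same-number pairs 8 correlated above 0.1 (range -0.226 to 0.313), and 7 of 15 arrays matched best with their own number. The values correlated were deviations from group means, which mirror each other where a group has 2 arrays. The 33 pairs are thus not independent, and no chance value was computed, so the check cannot decide whether samples were paired. With the replicate block phyAphyB dark minus WT dark gave 3 and WT Rc50 minus WT Rc15 gave 0; the other comparisons stayed within 1.5 times (1590, 1150, 2266, 2359, 664, 27, 495 and 2004, and 1164 shared).

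Centred log2 values, the literal reading of the planned order, moved the median of all probe sets by 0.15 in YHB dark minus phyAphyB dark, 0.12 in YHB dark minus WT dark and 0.12 in YHB dark minus WT Rc50, to 0.19, 0.16 and 0.18. Leaving out the scaling moved it by -0.26, -0.17 and -0.32 in these comparisons, 0.11 in WT Rc15 minus WT dark, -0.11 in YHB Rc50 minus WT Rc50 and 0.2 in YHB Rc50 minus YHB dark.

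With each array left out, counts ran from 1441 to 1641 in WT Rc50 minus WT dark, 1051 to 1205 in WT Rc15 minus WT dark, 2221 to 2343 in YHB dark minus phyAphyB dark, 2322 to 2465 in YHB dark minus WT dark, 0 to 8 in phyAphyB dark minus WT dark, 405 to 648 in YHB dark minus WT Rc50, 4 to 154 in YHB Rc50 minus WT Rc50, 390 to 490 in YHB Rc50 minus YHB dark, 0 to 6 in WT Rc50 minus WT Rc15, 1804 to 2066 for the difference between the responses and 1139 to 1216 for the shared response. Where this left 1 array in a group, that array is assumed to vary like the other groups.

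The shared response was 1179 with quantile normalization, 1158 without the dimmest probe sets, 1181 with trimmed-mean scaling, 959 without scaling and 888 with WT Rc15 in place of WT Rc50. Of 165 results for named genes, 139 passed in each of the 27 settings and 26 failed at least 1. Of 105 list results that passed, estimated correlation ended 73: 8 of 40 in the 9 planned lists and 65 of 65 in the lists added later. Quantile normalization ended 8 and added 6, the replicate block ended 2 and added 3, trimmed-mean scaling ended 2, no scaling ended 12 and added 14, and the mean of all probe sets of a gene ended 0. Dim probe sets are compressed by the added value of 16, which limits what can be seen near background.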

Other observations

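The genes and lists in this part were chosen only after their names or values had been seen. Among 23 nuclear-encoded factors of photosystem assembly, NDH and thylakoid electron transport, 14 rose in WT Rc50 minus WT dark (median 1.14, adjusted p = 4.68e-16), 14 in YHB dark minus phyAphyB dark (median 1.25, adjusted p = 1.28e-13) and 16 in YHB dark minus WT dark (median 1.51, adjusted p = 1.75e-14), and with an estimated correlation the adjusted p values were 0.0598, 0.0998 and 0.071. CaS, a thylakoid calcium-sensing protein gene, rose by 2.35, 3.09 and 3.41 in these comparisons, and PSB27, a photosystem II assembly factor gene, by 1.41, 2.08 and 1.98. Of 7 tubulin genes, 3 fell in the wild type under red light (adjusted p = 0.00033) and 5 in YHB dark minus phyAphyB dark (adjusted p = 6.85e-05), with adjusted p values of 0.0813 and 0.133 with an estimated correlation, and the list medians stayed negative under each scaling. TUB1 fell in both, at -3 and -4.07. TUB6 (-1.01), 1 of the 3 in the wild type, did not pass with pseudocount 64 (-0.96), centred log2 values (-0.94), array weights (-0.96), the replicate block (-0.92) or no scaling (-0.78), or without WT dark replicate 3 (-0.8) or WT Rc50 replicate 1 (-0.87). Of 28 expansin and xyloglucan genes, 8 fell and 1 rose in the wild type under red light (median -0.12, adjusted p = 0.125) and 9 fell and 1 rose in YHB dark minus phyAphyB dark (median -0.16, adjusted p = 0.00415, or 0.265 with an estimated correlation). Of 15 cellulase genes 3 fell in each (medians -0.2 and -0.16, adjusted p = 0.00484 and 0.00596, or 0.0813 and 0.149 with an estimated correlation). The medians in YHB dark minus phyAphyB dark turned to 0.03 and 0.2 with centred log2 values, where that of all probe sets was 0.19. Members that fell in both comparisons were the expansin gene EXPA9 at -1.88 and -2.94, XTH19 at -1.68 and -4.02, and the cellulase gene GH9C2 at -1.91 and -3.6. The multicopper oxidase gene LPR2 rose by 1.83 in WT Rc50 minus WT dark and by 1.69 in YHB dark minus phyAphyB dark.

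HYH, which encodes a bZIP transcription factor of light signalling, rose by 1.17 in WT Rc50 minus WT dark and by 2.8 in YHB dark minus phyAphyB dark, and fell in YHB Rc50 minus YHB dark, at -1.59. The clock gene GI changed by 0.03 in WT Rc50 minus WT dark, which did not pass, and fell in YHB dark minus phyAphyB dark, at -1.81, then rose by 2.39 in YHB Rc50 minus YHB dark; the difference between the responses was 2.36. SDP1, a seed oil lipase gene, rose by 1.19 and the carotenoid cyclase gene LYC by 1.35 in YHB dark minus phyAphyB dark. Their changes in WT Rc50 minus WT dark, 0.19 and 0.66, stayed under 2-fold (limma, adjusted p = 0.495 and 0.00418). So did the differences between the responses, -0.84 and -0.94 (limma, adjusted p = 0.0207 and 0.00552). In YHB dark minus WT Rc50 SDP1 was higher by 1.04, which passed, and LYC by 0.72, which stayed under 2-fold. HYH in WT Rc50 minus WT dark stayed under 2-fold with pseudocount 64 (0.55). In YHB dark minus phyAphyB dark SDP1 stayed under 2-fold with centred log2 values (0.98) and without scaling (0.57), and LYC without scaling (0.74).

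Of 14 cold- and dehydration-responsive genes, 4 were lower in YHB dark than in WT Rc50 (median -0.15, camera, adjusted p = 0.0317, or 0.313 with an estimated correlation). These groups also differed in temperature regime, whose effect cannot be told apart here. Among the 4 was LEA4-5 at -2.06, which stayed under 2-fold with pseudocount 64 (-0.97). LEA18, at -2.28, did not pass without YHB dark replicate 2 (-2.09), WT Rc50 replicate 1 (-2) or WT Rc50 replicate 2 (-2.56). By group of plastid-encoded genes, 13 of 33 photosystem, ATP synthase and Rubisco genes (adjusted p = 4.9e-08, or 0.313 with an estimated correlation) and 12 of 22 gene expression genes (adjusted p = 1.7e-11, or 0.268 with an estimated correlation) were higher in YHB dark than in WT Rc50.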
